A study of Homo sapiens with 6 samples.

How the data were processed

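Polyadenylated RNA was sequenced from 6 libraries of the human cholangiocarcinoma line HuCCT-1, 3 from cells kept with 6 nM JNJ-64619178 and 3 from cells kept with DMSO, each for 4 days. Per the labels' protocols, total RNA was extracted on an automated Maxwell instrument and libraries were made with a stranded Illumina mRNA ligation kit. The authors deposited 1 table of raw read counts per gene for all 6 libraries, with no normalization. Per the submitters' processing notes, FastQC 0.11.8, STAR 2.7.9a, featureCounts 1.6.0, edgeR and limma were used, with no role stated for any of them. The same notes name the mouse build GRCm39, while all 60649 rows of the table carry human Ensembl gene identifiers, so the build behind the counts is uncertain. The annotation release, the strand setting and the handling of reads that map to several places are not given in the sources used here. Counts of antisense and overlapping genes, of histone and ribosomal protein families and of pseudogenes are therefore uncertain, since reads could have been shared or counted on either strand.

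There were 44 identifiers that appeared again in a row with a total count of 0, and these second rows were dropped, which left 60605 genes. Of these, 60463 were matched to a symbol through the reference table of gene names. The other 142 held 0.037% of the counts, and 124 of them took a symbol from GENCODE release 29. Gene positions, types, GC content, exon numbers and exonic lengths were taken from GENCODE release 29 on GRCh38, which may differ from the annotation the authors used. The depth per library was 30194024, 28133746 and 30691914 counts with DMSO and 24315685, 28224911 and 23931991 with the inhibitor. All 3 libraries of each group differed by more than sampling noise (chi-square per degree of freedom 2.68 to 8.93 between replicates), so each was counted as 1 replicate. The first principal component of log2 CPM held 53.3% of the variance and separated the groups. The common biological coefficient of variation was 4.9%.

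Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total count 15), which left 17371, and libraries were scaled by TMM. Inhibitor and DMSO were compared with edgeR 4.0.16, fitting the group alone with glmQLFit and glmQLFTest, and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of the F statistic. CPM values were computed from the deposited counts with the TMM-scaled library sizes of the kept genes. The 42 gene lists with 1282 members in all, every one matched by symbol, were tested with camera (limma 3.58.1) on voom log2 CPM with a preset correlation between genes of 0.01. Beside it stood camera with an estimated correlation and fry. Members were counted past the threshold over all genes tested and adjusted over the list alone. The lists, the test, the rule for named genes and the alternatives were fixed before the data were examined.

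The text names genes by this rule. Among genes past the threshold with all inhibitor libraries on 1 side of all DMSO libraries, a mean log2 CPM of at least 1 and a symbol that is no clone, LOC, LINC or antisense name, the 12 with the largest fold change in each direction were taken. Among the same genes with at least 1.5-fold change, the 6 most abundant in each direction were added. The 4 members with the smallest p in each list served as examples, and all tested members of both lists of arginine methyltransferases and PRMT5 partners were named.

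The scripts were tested on simulated counts with 200 genes changed by known folds, drawn from the real means and library sizes. These genes were split evenly up and down, and the members of the chromatin modifier list were raised besides. In the real data 37.1% of the genes passed the threshold, so the simulation does not test scaling or error rates under such wide change. For the comparison of inhibitor against DMSO, edgeR, run on 17103 simulated genes, recovered 65% of the genes changed by 1.5-fold and 85% of those changed by 2-fold. It called 17 unchanged genes. Camera called the shifted list and 0 others, with counts drawn independently for each gene, so this step does not test the effect of correlated genes. 

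Alternatives were DESeq2 1.42.0, limma-voom, limma-trend with a prior count of 2, RLE and upper-quartile scaling, no filter on low counts, a filter of CPM above 1 in at least 3 libraries, the replicate number as a block, a test against a fold of 1.5 (glmTreat), and leaving out each library in turn. R 4.3.3 and Python 3.11.15 were used. The alternatives planned for normalized values did not apply, since the table held counts. Confidence intervals in the closing section are bootstrap intervals at 95% over genes or gene pairs, which are not independent replicates. Results for a few single genes are not reported here, and these genes were kept in all tests and list counts.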

Results

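Gene expression was measured by sequencing of polyadenylated RNA in HuCCT-1, an established human cell line of cholangiocarcinoma, a cancer of the bile ducts. Cells were kept for 4 days in 6 nM JNJ-64619178, an inhibitor of the arginine methyltransferase PRMT5, or in an equal volume of the solvent DMSO. PRMT5 adds symmetric methyl marks to arginine in histones and in spliceosomal Sm proteins, among other proteins. The series asked how PRMT5 inhibition alters gene expression in this cancer, and its design implies 1 comparison, inhibitor against DMSO, with 3 libraries in each group. Total gene counts per library ranged from 28133746 to 30691914 with DMSO and from 23931991 to 28224911 with the inhibitor (n = 3 each). The labels do not say whether the 3 replicates of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. All levels below are CPM, counts scaled to the library total, as mean ± SD over 3 libraries, and all fold changes are inhibitor over DMSO unless stated otherwise.

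After 4 days of inhibitor, several chemokines, collagens, integrins and interferon-stimulated genes were higher, and many divergent non-coding transcripts, histones and targets of the YAP and TEAD regulators were lower. PLCG1, a phospholipase that acts downstream of receptor tyrosine kinases, rose 4.18-fold, from 109 ± 4.65 to 458 ± 10.2 CPM. NEAT1, the long non-coding RNA at the core of paraspeckles, fell from 5150.3 ± 231 to 2339 ± 186 CPM, a 2.20-fold decrease. Of 17371 genes tested with edgeR's quasi-likelihood test, 3478 were higher and 2970 were lower at an adjusted p under 0.05, together 37.1% of the genes. Most changes were small. The median fold was 1.32 among the genes that rose and 1.27 (DMSO over inhibitor) among those that fell, and 368 rose and 280 fell by at least 2-fold. In 47% of the genes the 3 inhibitor libraries lay all above or all below the 3 DMSO libraries, against 10% expected by chance. With TMM scaling 53.9% of the calls were higher, and with upper-quartile scaling 40.6% were (2800 higher, 4099 lower), so the balance of directions depended on the scaling.

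**Figure D1:**
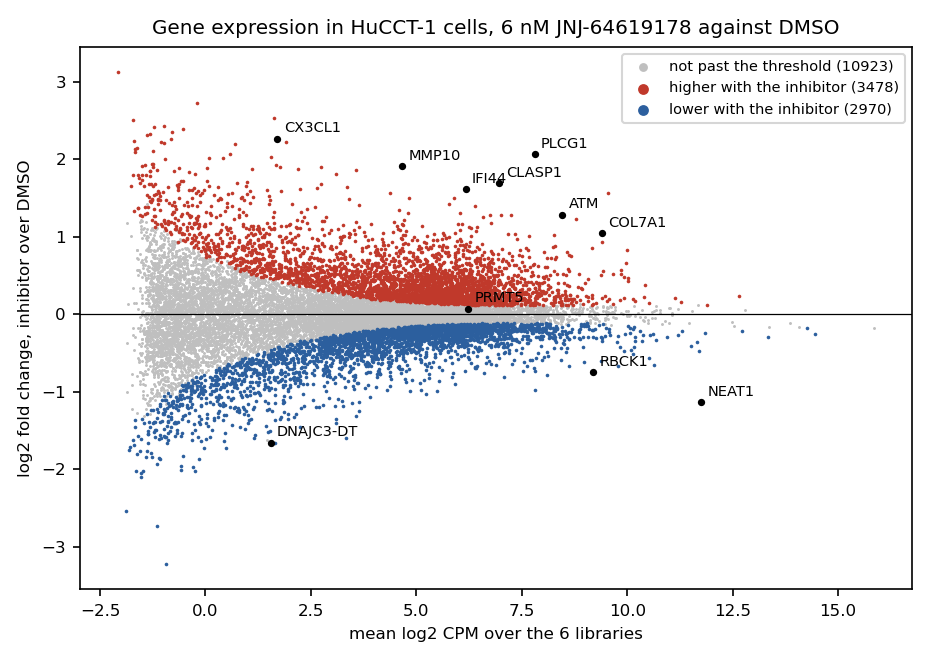
Log2 fold change (inhibitor over DMSO, vertical axis) against mean log2 CPM over the 6 libraries (horizontal axis) for each of the 17371 tested genes, with 3478 higher genes in red, 2970 lower genes in blue and the others in grey. PLCG1 at 2.06 stands out among abundant genes that rose, and NEAT1 at -1.14 among those that fell.

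PRMT5 itself did not pass the test. Its level was 73.1 ± 1.09 CPM with DMSO and 76.8 ± 1.18 CPM with the inhibitor (log2 fold change 0.07, SE 0.05, edgeR adjusted p = 0.25). The compound acts on the enzyme, so the level of its transcript does not test the labels as it would in a knockdown. PRMT5 (ENSG00000100462) lies on chromosome 14 at 22920511 to 22929585 in GENCODE release 29, on GRCh38. Among its partners, MTAP, which degrades a metabolite that blocks PRMT5, fell slightly (log2 fold change -0.20, adjusted p = 0.00229). COPRS, a histone-binding cofactor, rose by 0.23 on the log2 scale with an adjusted p of 0.0425, and lost its call in 7 of 11 alternatives, with adjusted p between 0.0249 and 0.282. These 7 were the fits without DMSO replicate 1, 2 or 3 (adjusted p 0.0979, 0.134 and 0.0856) and without JNJ replicate 2 (0.282, log2 fold change 0.14), the fit with the replicate number as a block (0.0587), DESeq2 (0.141) and upper-quartile scaling (0.128). CLNS1A (-0.09), MAT2A (-0.06), RIOK1 (0.10) and WDR77 (-0.02) did not pass. With upper-quartile scaling CLNS1A (-0.15, adjusted p = 0.0125) and MAT2A (-0.12, adjusted p = 0.0241) passed, and the list had 0 higher and 3 lower. In this list of 7, 1 member rose and 1 fell over all genes, and 0 rose and 1 fell adjusted over the list alone. At an edgeR unadjusted p under 0.05, 1 of the 7 was higher. The list was not called by camera (adjusted p = 0.747), and its median, -0.02, and its mean, 0.00, differed in sign.

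Of the other arginine methyltransferases, 8 were tested. PRMT7 rose (0.23, adjusted p = 0.00997), and NDUFAF7 (-0.22, adjusted p = 0.0172) and PRMT2 (-0.14, adjusted p = 0.0306) fell, with the same counts adjusted over the list alone. These 3 calls were fragile. PRMT7 did not pass without DMSO replicate 2 (adjusted p = 0.0736) or with upper-quartile scaling (0.0518). NDUFAF7 did not pass without DMSO replicate 1 (0.0644), JNJ replicate 1 (0.0565) or JNJ replicate 3 (0.0849). PRMT2 did not pass without DMSO replicate 1 (0.131), DMSO replicate 3 (0.0596), JNJ replicate 1 (0.0583) or JNJ replicate 3 (0.121), or with the replicate number as a block (0.0528). PRMT6 (-0.25), PRMT9 (-0.11), PRMT3 (-0.05), CARM1 (0.01) and PRMT1 (-0.0002) did not pass. With upper-quartile scaling PRMT6 passed (-0.31, adjusted p = 0.0401), with 0 higher and 3 lower in all. With TMM camera did not call the list (adjusted p = 0.504).

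The largest changes are given for called genes with a mean log2 CPM of at least 1, all inhibitor libraries on 1 side of all DMSO libraries and no clone, LOC, LINC or antisense name. The chemokine CX3CL1 rose from 1.47 ± 0.28 to 7.0 ± 1.31 CPM (log2 fold change 2.27, SE 0.18), and the chemokine CCL22 rose from 2.37 to 8.66 CPM. MMP10, a secreted protease of the extracellular matrix, rose from 13.2 ± 2.52 to 49.4 ± 3.62 CPM. The cytokine receptor IL7R (1.93), the endoribonuclease ENDOU (1.90), the cilium component RSPH1 (1.90), the kinase CAMK2B (1.86), the integrin subunit ITGB3 (1.68) and the interferon-induced OASL (1.63) rose too. CLASP1, which binds the growing ends of microtubules, rose from 69.7 ± 0.34 to 226 ± 15 CPM. The largest increase in this set, a log2 fold change of 2.54, was that of the keratin pseudogene KRT16P2, whose reads may be shared with near-identical keratin copies, so its value is uncertain. Among abundant genes, SLC25A37, an importer of iron into mitochondria, rose 1.77-fold, LARS1, the leucyl-tRNA synthetase, 1.80-fold, and ABCC3, an exporter of organic anions, 1.91-fold. PLCG1 (ENSG00000124181) lies on chromosome 20 at 41136960 to 41196801 (GRCh38).

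Of the 12 largest decreases in the same set, which leaves out antisense and LINC names, 8 were in transcripts that start beside a gene and run away from it, named with the suffix -DT. DNAJC3-DT fell from 5.07 ± 0.31 to 1.6 ± 0.16 CPM (log2 fold change -1.66, SE 0.17). USP34-DT (-1.37), ZKSCAN2-DT (-1.33), ST3GAL1-DT (-1.22), ANKRD42-DT (-1.22), CAPN10-DT (-1.20), MRPL20-DT (-1.20) and RNF139-DT (-1.19) fell as well. The strand setting of the counting is not given in the sources used here, so reads of such transcripts cannot be fully told from those of overlapping genes. DYNLT2, a dynein light chain gene, fell from 5.46 ± 0.50 to 1.74 ± 0.47 CPM, and the microRNA host gene MIR4453HG fell by 1.19 on the log2 scale. The mitochondrial transfer RNA gene MT-TP (-1.32) and the pseudogene RRP7BP (-1.25) also fell, the second with reads that may be shared with its parent gene. MT-TP was counted in polyadenylated RNA, at 5.35 CPM with DMSO and 2.15 CPM with the inhibitor. These counts need not reflect the level of the transfer RNA itself. Among abundant protein-coding genes, the keratin KRT81 fell from 1999.7 ± 81.5 to 1269 ± 52.4 CPM. The receptor phosphatase PTPRF (-0.66), the autophagy gene VMP1 (-0.61), RBCK1, a subunit of the linear ubiquitin ligase (-0.75), and the protease PRSS23 (-0.61) fell too.

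**Figure D2:**
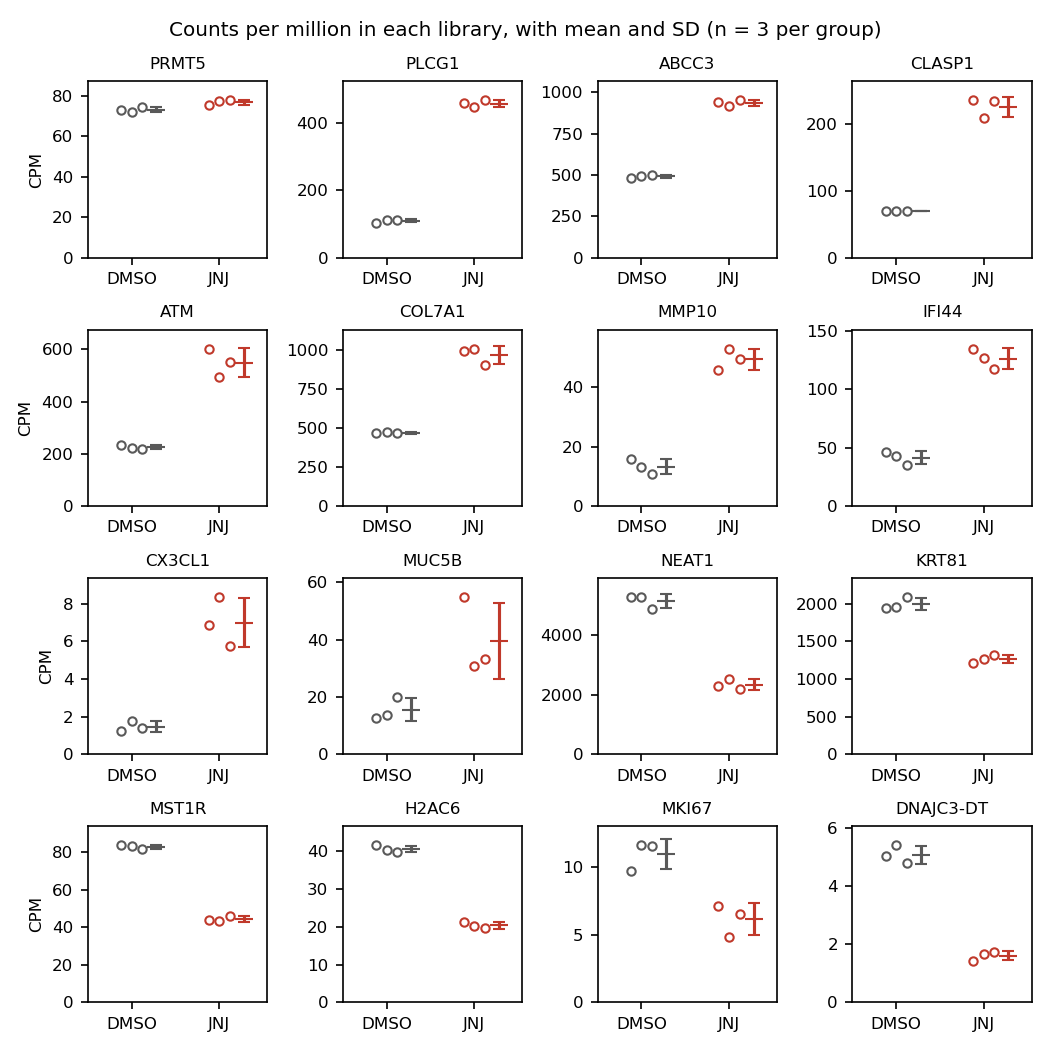
CPM (vertical axes, from 0) of 16 genes in each of the 3 DMSO libraries (grey) and 3 inhibitor libraries (JNJ, red), with the mean and SD of each group at the right of its points. The group means of PRMT5 were 73.1 and 76.8 CPM, while PLCG1 went from 109 to 458 CPM and NEAT1 from 5150.3 to 2339 CPM.

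Among the 42 gene lists fixed before the data were examined, camera with a preset correlation called 12, of which 6 were higher and 6 lower. With an estimated correlation camera called 0 of the 42, the lowest adjusted p was 0.532, and 2 lists had an unadjusted p under 0.05. The test fry, which asks whether the members of a list move one way and does not compare them with other genes, called 19, among them 8 of the 12. It did not call the lists of mitochondrially encoded, ribosomal protein, cholesterol synthesis and amino acid response genes. The other 11 by fry were the lists of DNA replication, mitosis, end joining, splicing regulators, hepatocyte, mucin, leukocyte, TGF-beta, NOTCH, fatty acid synthesis and apoptosis genes. With no filter on low counts camera called 7 more lists, those of mitosis, end joining, biliary epithelium, TGF-beta, NOTCH, fatty acid synthesis and nuclear oxidative phosphorylation genes. With upper-quartile scaling 11 list medians changed sign, those of the lists of p53 targets, excision and mismatch repair, snRNP genes, splicing regulators, squamous epithelium, MAPK feedback, ribosome biogenesis, ribosomal proteins, heat shock, glycolysis and apoptosis. The balance of member calls turned there from more higher to more lower in 5 lists, those of homologous recombination (4 higher, 5 lower), splicing regulators (14 and 16), MAPK feedback (7 and 10), glycolysis (6 and 7) and growth factor receptors (6 and 9).

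Interferon-stimulated genes rose as a group. Of 41 tested, 26 rose and 6 fell, with the same counts adjusted over the list alone, and the median log2 fold change was 0.39. IFI44 rose from 41.3 ± 5.76 to 126 ± 8.86 CPM, OAS3, a sensor of double-stranded RNA, rose by 0.80 and DDX60 by 0.90 on the log2 scale. Camera called the list (adjusted p = 4.47e-06), and the adjusted p was 0.576 with an estimated correlation. The antigen presentation list was not called (camera adjusted p = 0.312). In it 4 of 24 rose and 9 fell, against 5 and 9 adjusted over the list alone. The peptide transporter TAP1 (0.42), the class I regulator NLRC5 (0.49) and the protease CTSS (0.49) rose, and HLA-F fell (-0.49).

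NF-kB targets and inflammatory cytokines rose, with 20 of 31 members higher, 4 lower and a median of 0.33. The counts were the same adjusted over the list alone. TNFAIP3, a feedback inhibitor of NF-kB, rose from 313 ± 8.48 to 528 ± 18.4 CPM, the chemokine CCL2 rose 1.96-fold, and NFKB2 and the mitochondrial superoxide dismutase SOD2 rose by 0.61 and 0.60 on the log2 scale. The camera adjusted p was 4.47e-06, and the adjusted p was 0.532 with an estimated correlation.

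Genes of the extracellular matrix, integrins and laminins rose, with 21 of 38 higher, 6 lower and a median of 0.20. Adjusted over the list alone the counts were again 21 and 6. COL7A1, the collagen of anchoring fibrils, rose from 468 ± 5.64 to 967 ± 57.4 CPM. The integrin subunits ITGAV (0.87) and ITGB6 (1.09), which form a receptor that activates TGF-beta, rose as well. This list had a camera adjusted p of 7.75e-05, with an adjusted p of 0.532 with an estimated correlation. In the mesenchymal and epithelial-mesenchymal transition list 7 of 17 rose and 1 fell, over all genes and adjusted over the list alone, and the median was 0.31. On voom values its median was 0.39, and 0.13 without DMSO replicate 2, where the call held (adjusted p = 0.0448). The members that led it were collagens. COL6A1 rose from 289 ± 10.0 to 680.4 ± 15 CPM, and COL1A1 (0.78), COL6A2 (0.56) and COL5A2 (0.72) rose with it. By camera the adjusted p was 0.0272, and the adjusted p was 0.532 with an estimated correlation. TGF-beta targets were not called (camera adjusted p = 0.136), with 8 of 19 higher and 2 lower, or 8 and 3 adjusted over the list alone. TGFB1 (0.47) and TGFBI (0.38) rose and the BMP antagonist NOG fell (-0.52).

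Targets of YAP and TEAD, the transcriptional regulators of the Hippo pathway, fell, with 11 of 21 lower, 3 higher and a median of -0.21. Adjusted over the list alone 12 were lower and 3 higher. ANKRD1 fell from 108 ± 7.32 to 66.6 ± 1.24 CPM and F3, which encodes tissue factor, fell from 3931 ± 71.4 to 2818 ± 96.2 CPM, while ASAP1 (0.47) and ARHGEF17 (0.39) rose. Camera called the list (adjusted p = 0.00254), and the adjusted p was 0.532 with an estimated correlation.

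Chromatin modifiers rose, with 26 of 52 higher and 4 lower (27 and 4 adjusted over the list alone), by small amounts (median 0.14). With upper-quartile scaling the median was 0.08, with 20 higher and 10 lower. The histone methyltransferase genes EHMT2 (0.84), SETDB1 (0.70) and EZH2 (0.53) and the demethylase gene KDM5A (0.54) rose. The camera adjusted p was 0.00272, and the adjusted p was 0.576 with an estimated correlation. Camera compared the list with all tested genes. Of all protein-coding genes with 40 to 386 annotated exons, 37.1% rose and 13.4% fell, with a median of 0.09. Neither this list nor the others were matched on exon number, so the call does not tell its rise from that of many-exon genes. Replication-dependent histones fell, with 9 of the 21 tested lower (11 adjusted over the list alone), no member called higher and a median of -0.51. H2AC6 fell from 40.7 ± 0.90 to 20.4 ± 0.86 CPM, and H4C8 (-0.79), H2BC9 (-0.83) and H1-2 (-0.55) fell. Most such messages lack a poly(A) tail, so in polyadenylated RNA these counts cover only part of them, and near-identical copies share reads. This list had a camera adjusted p of 0.00244, with an adjusted p of 0.532 with an estimated correlation.

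Mitosis genes were not called as a list (camera adjusted p = 0.0792). The proliferation marker MKI67 fell from 10.9 ± 1.09 to 6.13 ± 1.2 CPM, and TOP2A (-0.71), CCNA2 (-0.53) and BUB3 (-0.21) fell. In all, 6 of 37 fell (5 adjusted over the list alone) and no member was called higher. This list passed without DMSO replicate 1 (adjusted p = 0.0432), without JNJ replicate 3 (0.0392), with no filter on low counts (0.00841) and with fry (0.0273). DNA replication genes went both ways, with 7 of 40 higher and 4 lower, or 6 and 3 adjusted over the list alone. The helicase subunit MCM7 rose from 134 ± 2.18 to 227 ± 7.06 CPM, and the polymerase genes POLD1 (0.66), POLD3 (0.51) and POLE (0.33) rose. The list was not called (camera adjusted p = 0.55), and its median, -0.003, and mean, 0.07, differed in sign. Among cyclins, CDKs and CDK inhibitors 4 of 31 rose and 5 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.676). The repressor E2F7 (-0.42) and RBL1 (-0.59) fell, and CDK13 (0.27) and CDKN1A (0.22) rose.

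Some DNA repair genes rose. ATM, the kinase that signals DNA breaks, rose from 226 ± 8.45 to 549.8 ± 54.6 CPM, and SLX4 (0.51), ATR (0.29) and MRE11 (0.28) rose in the homologous recombination and Fanconi list. There 6 of 39 rose and 3 fell, or 5 and 2 adjusted over the list alone, and camera did not call it (adjusted p = 0.889). Its median, -0.002, and mean, 0.003, differed in sign. In the end-joining list 6 of 15 rose and 1 fell, with the same counts adjusted over the list alone. PAXX rose from 34.3 ± 1.62 to 70.7 ± 6.64 CPM, NHEJ1 (0.67) and RIF1 (0.30) rose and POLM fell (-0.30). The list was not called over all libraries (camera adjusted p = 0.121) but passed without JNJ replicate 2 (adjusted p = 0.0417), with no filter on low counts (0.0363) and with fry (0.0122). In the base, nucleotide excision and mismatch repair list 8 of 32 rose and 3 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.462). The glycosylase genes MUTYH (1.61) and NEIL1 (0.83), the damage sensor DDB2 (0.75) and the helicase ERCC3 (0.37) rose.

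The p53 target list was not called (camera adjusted p = 0.967). Of 30 members 5 rose and 5 fell, with the same counts adjusted over the list alone. DDB2 and the apoptosis effector BAX (0.41) rose, and SESN2 (-0.27) and TP53I3 (-0.48) fell. In the apoptosis list 9 of 31 rose and 5 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.352). The pro-apoptotic PMAIP1 rose from 42.3 ± 2.29 to 87.3 ± 3.32 CPM, and BMF rose (0.79). The apoptosis inhibitor BIRC3 also rose (0.40), while the anti-apoptotic BCL2L1 fell from 335 ± 2.07 to 230.4 ± 4.94 CPM.

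Splicing regulators moved in both directions, with 16 of 45 higher and 11 lower, or 16 and 12 adjusted over the list alone (camera adjusted p = 0.377). HNRNPH1 rose from 797 ± 26.9 to 1263 ± 12 CPM, and LUC7L (0.89), RBM39 (0.57) and SF3B1 (0.51) rose. Of the snRNP core and assembly genes, whose Sm proteins are methylated by PRMT5, 3 of 35 rose and 4 fell, or 3 and 3 adjusted over the list alone (camera adjusted p = 0.94). The helicase SNRNP200 rose (0.36), and SNRPA (-0.32), LSM7 (-0.37) and GEMIN4 (-0.30) fell.

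Cytosolic ribosomal protein genes were higher by a small amount, with 16 of 72 higher, 2 lower (14 and 2 adjusted over the list alone) and a median of 0.05 that turned to -0.004 with upper-quartile scaling (6 higher and 4 lower). RPL22 (0.34), RPL26 (0.38), RPL7 (0.19) and RPS15 (0.20) rose, with reads that may be shared with their many pseudogenes. By camera the adjusted p was 0.0398, and the adjusted p was 0.802 with an estimated correlation. The call was also lost without DMSO replicate 1 (adjusted p = 0.269, voom median 0.02), DMSO replicate 2 (0.274) or JNJ replicate 2 (0.396, voom median 0.03), with upper-quartile (0.542) or RLE scaling (0.0662), a stricter filter on low counts (0.0819), a replicate block (0.0576) or fry (0.298). Ribosome biogenesis and MYC targets were not called (camera adjusted p = 0.94), with 5 of 40 higher and 5 lower, or 4 and 5 adjusted over the list alone, and 2 and 9 with upper-quartile scaling. The nucleolar methyltransferase NOP2 rose from 3.15 ± 0.17 to 7.24 ± 0.47 CPM and PPAN rose (0.66), and NHP2 (-0.30) and CAD (-0.19) fell.

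Mitochondrially encoded genes fell, with 7 of 15 lower (11 adjusted over the list alone), no member called higher and a median of -0.17. MT-CO3 fell from 11415 ± 807 to 9332 ± 654 CPM and MT-ND6 fell by 0.29 on the log2 scale. The share of all counts from the mitochondrial genome was 19.59 ± 1.52% with DMSO and 17.54 ± 1.2% with the inhibitor, and the libraries overlapped (17.84% to 20.61% against 16.76% to 18.92%). Camera called the list (adjusted p = 0.00272), and the adjusted p was 0.678 with an estimated correlation and 0.238 with fry. Nuclear genes of oxidative phosphorylation were not called (camera adjusted p = 0.211), with 4 of 48 higher and 14 lower, and the same counts adjusted over the list alone. NDUFA10 (0.64) and NDUFV1 (0.39) rose, and ATP5F1B (-0.24) and UQCRC1 (-0.24) fell.

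Lysosome and autophagy genes fell, with 15 of 31 lower and 3 higher (17 and 3 adjusted over the list alone) and a median of -0.12. The hydrolase gene GAA (-0.33) and the autophagosome marker MAP1LC3B (-0.39) fell. The camera adjusted p was 0.00244, and the adjusted p was 0.532 with an estimated correlation. Genes of the amino acid response and unfolded protein response fell, with 14 of 33 lower and 6 higher (15 and 6 adjusted over the list alone) and a median of -0.11. The stress transcription factor DDIT3 (-0.49) and the chaperones PDIA4 (-0.28) and HSP90B1 (-0.29) fell, and EDEM1, which directs misfolded proteins to degradation, rose (0.43). This list had a camera adjusted p of 0.0362, with an adjusted p of 0.665 with an estimated correlation. It was 0.0813 without DMSO replicate 1, 0.0988 without JNJ replicate 1 and 0.0809 with fry. The voom median of -0.10 was -0.06 without JNJ replicate 1, -0.17 without JNJ replicate 2 and -0.16 with upper-quartile scaling. Heat shock and chaperone genes were not called (camera adjusted p = 0.319), with 3 of 18 higher and 1 lower, also adjusted over the list alone. HSF1 (0.68), HSPH1 (0.38) and HSPB1 (0.27) rose and DNAJB4 fell (-0.44).

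Cholesterol synthesis genes fell, with 9 of 25 lower and 3 higher (10 and 3 adjusted over the list alone) and a median of -0.14. The enzymes EBP (-0.56) and MSMO1 (-0.44) fell, and lanosterol synthase LSS rose (0.44). By camera the adjusted p was 0.0388, and the adjusted p was 0.678 with an estimated correlation. It was 0.122 without DMSO replicate 1 (voom median -0.07), 0.0616 without JNJ replicate 1, 0.052 with a stricter filter on low counts and 0.0809 with fry. Fatty acid synthesis genes were not called (camera adjusted p = 0.183), with 4 of 23 higher and 8 lower, and the same counts adjusted over the list alone. SREBF1 (-0.40), ACSL3 (-0.45) and DGAT1 (-0.42) fell and ACSL5 rose (0.44). In the glycolysis and hypoxia list 7 of 34 rose and 4 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.579). VEGFA fell from 1142 ± 3.05 to 824 ± 4.76 CPM, and ANGPTL4 (0.89), PFKFB4 (0.80) and NDRG1 (0.44) rose. NRF2 targets were not called (camera adjusted p = 0.481). Of 22 members 3 rose and 7 fell, with the same counts adjusted over the list alone, among them ABCC3, which rose, and NQO1 (-0.39) and GCLC (-0.38), which fell. Their median was -0.04, while fry gave the opposite direction (adjusted p = 0.728).

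The secreted mucin gene MUC5AC rose from 198 ± 43.0 to 348 ± 49.9 CPM, MUC5B from 15.5 ± 3.97 to 39.7 ± 13.3 CPM, and MUC6 (0.85) and MUC2 (0.88) rose with them. These 4 genes lie on chromosome 11 between 1012821 and 1262172 (GRCh38) and hold repeats that can share reads. In the mucin and gastrointestinal list 8 of 18 rose, no member was called lower (1 with upper-quartile scaling), with the same counts adjusted over the list alone, and camera did not call it (adjusted p = 0.107). Cholangiocyte and biliary epithelium genes were not called (camera adjusted p = 0.306), with 4 of 27 higher and 7 lower, or 4 and 10 adjusted over the list alone. The biliary keratins KRT7 (3646 ± 100.2 to 2842 ± 99.2 CPM) and KRT18 (-0.29) and the claudin CLDN7 (-0.27) fell, and the anion exchanger SLC4A2 rose from 143 ± 7.46 to 288 ± 9.59 CPM. In the squamous and stratified epithelium list 5 of 21 rose and 2 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.585). PKP1 (0.96), TGM1 (0.62) and KLK10 (0.43) rose.

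The signalling lists of this paragraph were not called. EGR1 rose from 35.6 ± 3.34 to 100.4 ± 10.8 CPM, FOS rose from 6.67 ± 0.29 to 13.3 ± 1.39 CPM, and PHLDA1 and ETV4 rose by 0.38 each. In that MAPK feedback and immediate early list 8 of 32 rose and 7 fell, or 8 and 8 adjusted over the list alone (camera adjusted p = 0.676). MST1R, a receptor tyrosine kinase, fell from 82.9 ± 1.18 to 44.4 ± 1.47 CPM, EREG fell (-0.37) and NRG1 rose (0.48). In the growth factor receptor and ligand list 11 of 23 rose and 7 fell, or 12 and 9 adjusted over the list alone (camera adjusted p = 0.907). Its median was 0.15, while fry gave the opposite direction (adjusted p = 0.151). In the NOTCH and HES list 8 of 14 rose and 1 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.136). With upper-quartile scaling 4 rose and 1 fell. NOTCH2 (0.26) and JAG2 (0.26) rose and LFNG fell (-0.23). Of 12 WNT targets 1 rose, CD44 (0.21), and 4 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.306). AXIN2 (-1.02), NKD2 (-0.55) and DKK1 (-0.25) fell. Without JNJ replicate 1 they did not pass (adjusted p = 0.094, 0.101 and 0.0675), with DKK1 at -0.14, and NKD2 did not pass with DESeq2 (0.0588).

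Markers of other cell types were few and mostly low. Of 6 hepatocyte genes tested, ASGR1 (1.6 to 3.38 CPM) and CYP2E1 (32.2 to 38.0 CPM) rose, and the most abundant, SERPINA1, did not pass (345 to 373 CPM), except with limma-voom (adjusted p = 0.0457) and without JNJ replicate 1 (0.0107). Adjusted over the list alone 3 rose, and the list was not called (camera adjusted p = 0.174). Of 5 leukocyte genes LAPTM5 (0.18 to 0.70 CPM) and CD14 (2.35 to 3.40 CPM) rose, 3 rose adjusted over the list alone, and the list was not called (camera adjusted p = 0.306). CD14 did not pass without DMSO replicate 1 (adjusted p = 0.09), DMSO replicate 2 (0.118) or JNJ replicate 3 (0.072), or with DESeq2 (0.0847). Of 3 endothelial genes ESAM rose (8.60 to 10.5 CPM, edgeR adjusted p = 0.0391), also adjusted over the list alone, and lost its call in 7 of 11 alternatives. These were DESeq2 (0.125), upper-quartile scaling (0.1) and all fits without 1 library except that without DMSO replicate 1, with adjusted p up to 0.244 without DMSO replicate 3, where the log2 fold change was 0.17. The endothelial list was not called (camera adjusted p = 0.481).

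**Figure D3:**
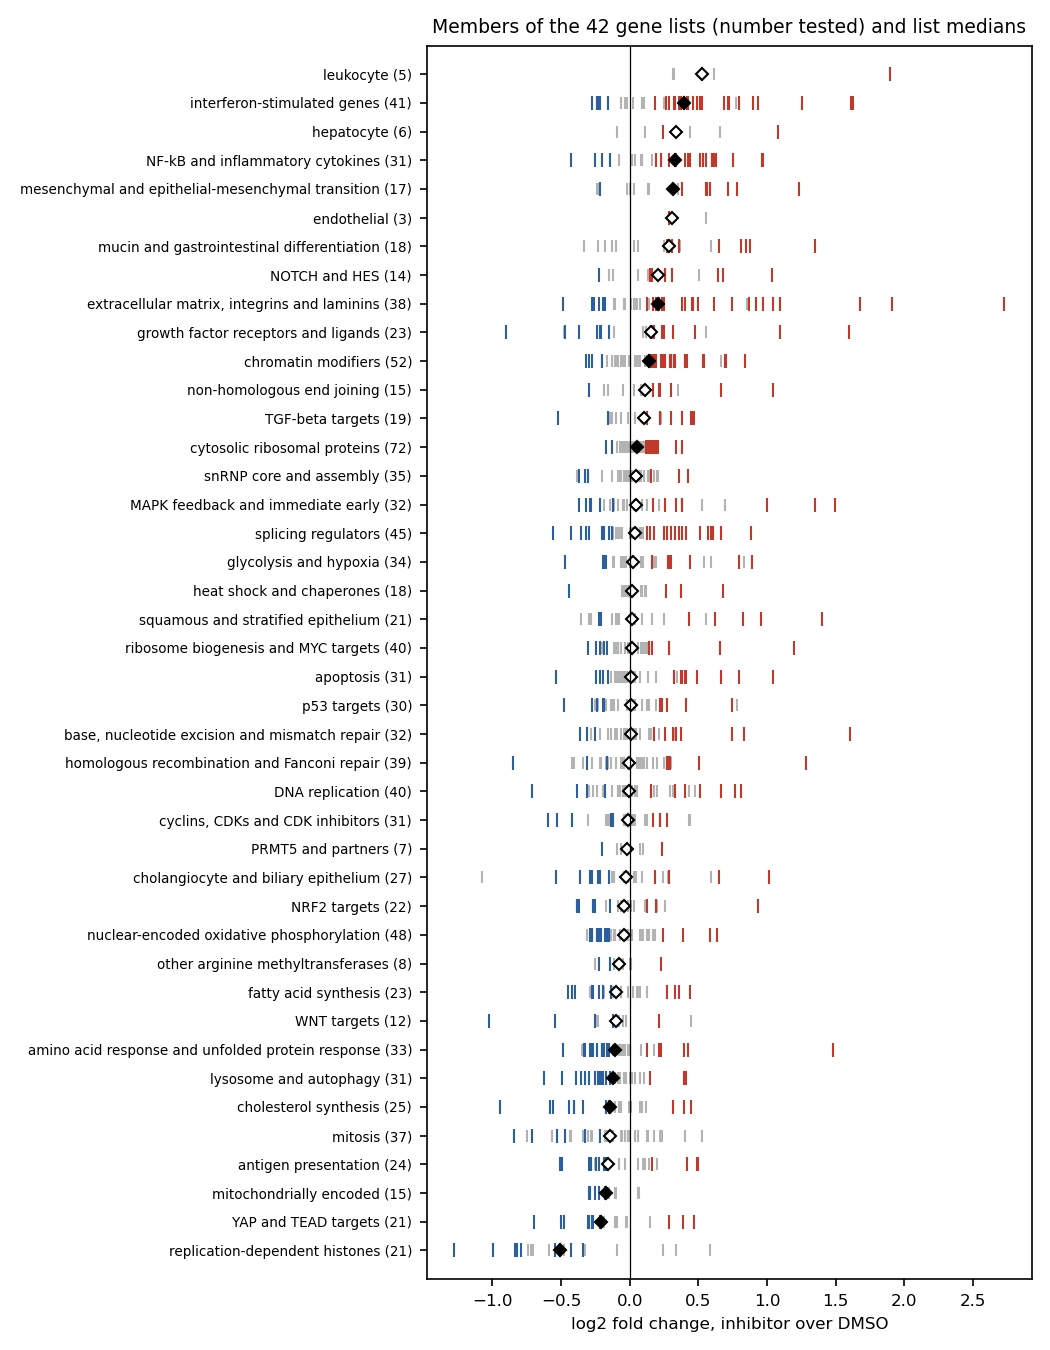
Log2 fold change (inhibitor over DMSO, horizontal axis) of each tested member of the 42 gene lists, with the number tested in brackets. Ticks are members (red higher, blue lower, grey not past the threshold) and diamonds are list medians, filled for the 12 lists that camera called with a preset correlation. The medians run from -0.51 in replication-dependent histones to 0.52 in leukocyte genes, and the latter list was not called.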

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

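All alternatives were planned before the data were examined. Counts of genes higher and lower with the inhibitor were 3478 and 2970 with edgeR and TMM. They stayed within 1.5 times of these under DESeq2 (2790 and 2413), limma-voom (3464 and 2978), limma-trend (3452 and 2993), RLE (3371 and 3099), upper-quartile scaling (2800 and 4099), no filter (3253 and 3030) and the CPM filter (3348 and 2893). Leaving out 1 library gave 2879 to 3345 higher and 2425 to 2752 lower genes. A test against a fold of 1.5 left 326 higher and 128 lower, since it asks for more than a difference from 0. Upper-quartile scaling shifted the median log2 fold change of all genes by -0.0586. DESeq2 and edgeR shared 5164 calls, and upper-quartile and TMM scaling shared 5770.

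The number of lists called by camera was 12. It was 19 with no filter on low counts, 19 with fry and 0 with an estimated correlation, where 2 lists had an unadjusted p under 0.05, and 10 to 13 without 1 library. The cause of these shifts was not tested. Of the 12, 9 kept their call in every camera fit with the preset correlation. Named genes were followed in 11 alternatives, DESeq2, limma-voom, RLE and upper-quartile scaling, the replicate block and the fits without 1 library. Limma-trend, the other filters and the test against a fold of 1.5 were not followed gene by gene. Of 203 named genes 187 were called. In the 11 alternatives none of these reversed, and 12 lost their call in at least 1. Of the others, 5 were called in at least 1 of the 11, CLNS1A, MAT2A, PRMT6, SERPINA1 and CSF1R.

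No pairing of the samples by replicate number was seen over all genes tested. The labels do not say whether equal numbers mark a shared passage or day, and low correlations cannot exclude it. The deviations of libraries with the same number correlated at -0.018, -0.014 and 0.002, and 0 of 6 libraries correlated best with their own number. With a replicate block 3311 genes were higher, 2821 lower and 11 lists called.

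Reversals occurred only in lists and genes that were not called, and the cause was not tested. List values here are medians on voom log2 CPM, and a list counts as reversed where its test turned. P53 targets (0.008) gave -0.051 with upper-quartile scaling, -0.004 with no filter, 0.003 with the CPM filter, 0.009 with the replicate block and -0.013 to 0.03 without 1 library. The snRNP list (0.047) gave -0.012 with upper-quartile scaling and 0.017 to 0.063 without 1 library. Ribosome biogenesis and MYC targets (0.013) gave -0.046 with upper-quartile scaling, 0.001 with no filter and -0.008 to 0.031 without 1 library. Homologous recombination and Fanconi repair (-0.003) ranged from -0.044 to 0.026 without 1 library. NRF2 targets gave -0.031 beside fry. Growth factor receptors and ligands (0.152) gave 0.094 with upper-quartile scaling, 0.139 with no filter and 0.152 beside fry. CARM1 (0.0057) gave -0.0031 with DESeq2, -0.0015 with RLE, -0.053 with upper-quartile scaling and -0.0123 to 0.0241 without 1 library. Without 1 library WDR77 ranged from -0.0799 to 0.0153, PRMT3 from -0.1179 to 0.0616 and PRMT1 from -0.0207 to 0.0253.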

Other observations

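The patterns below were noticed in the data and then tested on the same data. The tests of unspliced RNA, of a response shared by neighbours on either strand (all pairs and protein-coding pairs) and of other splits of the libraries were chosen only after the results were seen. The model of divergent transcripts with GC content, length and exon number, and the class medians under other scalings, were added last, when the fall of these transcripts and the other tests of it were known. Several non-coding transcript classes leaned lower with the inhibitor. Of 242 tested transcripts with the suffix -DT, which start beside a gene and run away from it, 89 fell and 7 rose, with a median log2 fold change of -0.48. Of 573 antisense transcripts with the suffix -AS, 152 fell and 30 rose (median -0.23), and of 828 long intergenic RNAs 169 fell and 85 rose (median -0.12). Of 13061 protein-coding genes 2196 fell and 3135 rose, with a median of 0.02 that turned to -0.04 with upper-quartile scaling, under which the -DT median was -0.54 and the -AS median -0.29. Of 12 mitochondrial transfer RNA genes 5 fell, with a median of -0.57. They were counted in polyadenylated RNA with an unknown strand setting, so these counts need not reflect the levels of the transfer RNAs. Not all non-coding classes leaned lower with TMM. The median was 0.04 in 621 processed pseudogenes and 0.03 in 41 small nucleolar RNAs, the latter with an interval (-0.281 to 0.076) that gives no direction. Upper-quartile scaling shifted the median of all genes by -0.0586, more than the size of either value.

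The fall of divergent transcripts exceeded that of protein-coding genes (Fisher's exact test over genes, two-sided, odds ratio 2.88, p = 1.76e-13). Low abundance did not give it, since the lowest median among 10000 sets of protein-coding genes matched on abundance was -0.051, and in a linear model with GC content, exonic length, exon number and abundance the divergent term kept -0.462 (95% interval -0.536 to -0.391, against -0.538 without them). Unspliced RNA or genomic DNA in the DMSO libraries would also lower sense intronic genes, and their median was -0.121 (-0.189 to -0.04), a smaller fall. These genes were not matched to the divergent transcripts on abundance, so a contribution of such RNA or DNA stays open. The partner genes that share the promoters had a median of 0.018 (-0.023 to 0.053). In 187 of 239 pairs the divergent transcript had a lower log2 fold change than its partner. The RNA of the partners thus did not fall as a set, and across the 239 pairs the fold changes did not correlate (Spearman rho -0.004). Promoter activity itself was not measured, and no other biological explanation was tested. The unknown strand setting of the counts stays open.

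Neighbouring genes on the same strand, at most 10 kb apart, had log2 fold changes that correlated across pairs (Spearman rho 0.242 over 2503 pairs, 95% interval 0.199 to 0.281, permutation p = 1e-04, the smallest the permutations can give). Genes are not independent replicates. Reads shared within gene families do not account for it alone, since without pairs whose symbols share their first 3 letters rho was 0.205 (0.165 to 0.244), and a shared response of the neighbourhood would also appear in genes that face each other, where rho was 0.035 (-0.025 to 0.096). Between protein-coding genes alone rho was 0.154 (0.105 to 0.201) on the same strand, 0.026 (-0.04 to 0.091) for genes that face each other and 0.092 (0.016 to 0.165) for genes that face apart, so for these pairs a response shared across strands stays open. Transcription that reads through from the upstream gene may contribute, but rho was 0.051 higher where the downstream gene was at least 4 times less abundant than where it was at least 4 times more abundant, with an interval of -0.05 to 0.164. That interval keeps read-through open, and no biological explanation was tested further.

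Protein-coding genes with an annotated retained-intron transcript were more often higher, 2148 of 7494 (28.7%) against 987 of 5569 (17.7%; Fisher's exact test over genes, two-sided, p = 1.73e-48). General gene features could give this, since the difference of means of 0.068 shrank to 0.01 (-0.004 to 0.023) in a linear model with GC content, exonic length, exon number and abundance. Exonic length and exon number included the retained-intron transcripts themselves, so part of this shrinkage may be built in. Of genes with 40 to 386 annotated exons 37.1% rose and 13.4% fell, and of those with 1 to 14 exons 12.8% rose and 19% fell. Reads inside retained introns may add a little, as the fold change rose weakly with the share of exonic bases found only in such transcripts (Spearman rho 0.054, 0.031 to 0.075). The median of genes with a retained-intron transcript was 0.047 (0.031 to 0.069) above that of genes with decay transcripts only. These sets were not matched on exon number, which counts the exons of all annotated transcripts of a gene. The difference therefore does not set richer annotation aside.

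The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. Of the 10, 1 gave as many genes, the real split with 6448, and the highest other gave 0 with edgeR. At an unadjusted edgeR p under 0.05 the real split had 7847 genes. The others had 181 to 396, which is under 0.05 of the genes tested. For lists called by camera with the preset correlation, 1 of the 10 splits gave as many, the real one with 12, and the others gave 2 to 8. Lists were thus called in every split, also where no gene passed the threshold. Each other split sets 2 DMSO libraries and 1 inhibitor library against the reverse. Part of the treatment difference stays between its groups, and the rest widens the spread within them. That spread lowers the gene calls, so the 0 genes of the other splits do not measure chance.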
